A study of Mus musculus with 2 samples.

How the data were processed

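Single-cell RNA sequencing of ovaries from C57BL mouse pups at postnatal day 3 was read from 2 libraries of the 10x Genomics 3′ assay, 1 library per treatment group. Both groups received melatonin (MLT) through the mother from embryonic day 16.5. In the DEHP_MLT group the mother was also gavaged with DEHP, a phthalate plasticizer, and in the MLT group DMSO took the place of DEHP. The number of pups or ovaries in each library is not given in the sources used here. Per the labels, the authors ran Cell Ranger, with no version stated, and Seurat 4.2.0, and named mm9 as the genome build. The authors deposited 1 table per library of raw counts, that is UMI counts (unique molecular identifiers) per gene and barcode, which are whole numbers with no normalization. Of the gene symbols, 98.2% were found in the GENCODE vM21 annotation, which is not built on mm9, so no coordinates are given.

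The labels and the deposited tables conflict. The table attached to the sample titled MLT carries DEHP_MLT in its own name, and the table attached to the sample titled DEHP_MLT carries MLT. The sample titles were followed throughout, and "labelled MLT" and "labelled DEHP_MLT" refer to those titles. The group field of the samples goes with the titles, since it reads NA for the sample titled MLT and DEHP for the sample titled DEHP_MLT. The counts themselves do not settle which is right, and every direction between the groups would reverse if the names of the tables were the correct ones.

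The 21018 genes present in both tables were compared. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 5199 of 5277 in the library labelled MLT and 4819 of 4819 in the library labelled DEHP_MLT. Scrublet, run per library in scanpy 1.11.5 with an expected rate of 6%, called 0 and 3 barcodes as doublets. A caller that marks 0.0623% of the barcodes of a library has not worked here, and the 10015 remaining cells must be taken to contain doublets. Counts were scaled per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 0.5 (igraph 0.11.9), without integration of the libraries, into 20 clusters. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

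Clusters were named from markers of 11 cell types fixed before the data were examined. A name required at least 3 markers, each in at least 25% of the cluster's cells and higher there than elsewhere by at least 1.0 on the log2 scale. This naming rule was written after the data were seen. So was the rule that a cluster with both germ and granulosa or surface markers at 0.15 or more of the level in their own clusters is called mixed and kept out of the named classes. Before that rule, a cluster with low median UMIs for its library and none of its class markers among its leading genes was left unnamed. All class names mean cells resembling that type by its markers. The markers Insl3, Hbb-b1, Hbb-b2 and Hbb-y were in neither table.

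With 1 library per group no replicate spread exists, cells are not replicates, and no test, p-value or count of changed genes was computed. Shares of cells carry exact Clopper-Pearson 95% intervals. UMIs were summed over the cells of a class in each library and scaled to the class total as CPM with exact Poisson 95% intervals. All intervals cover counting error only. Ratios are log2 of DEHP_MLT over MLT after adding 1 CPM, so a positive value means a higher level in the library labelled DEHP_MLT, and large differences of weakly expressed genes are understated. Fold values of single genes in mixed cells over germ cells of the same library were also taken after adding 1 CPM to both. Where a library held 0 UMIs of a gene, a floor of 3 counts over the class was used.

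Genes were named by a rule fixed before the data were examined. In germ and granulosa cells these are the 10 highest and 10 lowest ratios among genes with at least 50 CPM in either library, intervals apart and at least a 1.5-fold ratio. Mitochondrial, ribosomal protein and haemoglobin genes and unnamed gene models were left out of the ranking. In other classes with at least 100 cells per library the 3 highest and 3 lowest were taken. Of each gene list up to 4 members at the extremes and the most abundant member could be named, and of the genes at least 1.5-fold apart the same way in all 6 classes up to 10. Some genes that the rule names are not reported.

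The 24 gene lists fixed before the data were examined cover meiotic prophase, oocyte transcription factors, growing-oocyte products, early germ cell and pluripotency genes, bipotential pregranulosa and epithelial pregranulosa genes, Notch, BMP and TGF-beta, and PI3K and mTOR signalling. They also cover antioxidant defence, apoptosis, autophagy, DNA damage repair, proliferation, steroidogenesis, cholesterol synthesis, PPAR and lipid genes, melatonin and hormone receptors, the circadian clock and DNA and histone methylation. The remaining lists are endoplasmic reticulum (ER) stress, immediate-early and heat shock genes, glycolysis and hypoxia, and Y-linked genes. A list's median ratio over members with at least 10 CPM in either library was set against 10000 random lists of the same size matched on expression. Its percentile describes these libraries and is not a test of the treatment. The list members Gcna, H1f8, Grem1, Ctgf, H2ax, Mtnr1a, Asmt, Cyp1a1 and Bmal1 were in neither table, some of them as later names of genes present under an older symbol. None of the 4 Y-linked genes was present, so 0 members were measured and that list has no result.

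For the cell cycle and the germ cell stages each cell was thinned at random to 2000 UMIs. For the per-cell share of interferon-induced and MHC (major histocompatibility complex) transcripts, 34 genes were chosen after the results were seen, and cells were clustered again without those and related genes so that the genes did not define the classes. Cells with at least 60 UMIs of the set per 10000 were counted, a level also set after the results were seen.

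Alternatives fixed before the data were examined were all deposited barcodes, a stricter filter of 1000 genes and 10% mitochondrial UMIs, doublets kept, Leiden resolution 1.0, each library clustered on its own, 10 CPM as pseudocount, TMM scaling (edgeR 4.0.16 in R 4.3.3), a total without mitochondrial, ribosomal protein and haemoglobin genes, equal weight per cell, list members from 1 CPM, no thinning, thinning to 1000 UMIs and sub-clustering at 0.6 in place of 0.3. Added after the data were seen were a floor of 6923 UMIs in both libraries, removal of the 6% of barcodes with the highest doublet scores, clustering without interferon and MHC genes, shares outside erythroid cells, germ cells with the mixed germ-led cluster, classes without their interferon-led cluster, and the pericyte and smooth muscle clusters each alone. TMM scaling moved the median ratio over all genes from -0.03 to 0.12 in germ cells, from -0.13 to -0.04 in granulosa cells, from -0.16 to -0.04 in surface cells, from -0.09 to 0.06 in stroma, from -0.06 to 0.03 in perivascular cells and from -0.12 to -0.01 in endothelial cells.

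The naming rule was tested on simulated data with the real depths, with both libraries drawn from 1 pooled profile and counting error only. The simulation therefore says nothing of differences between libraries of the same treatment. Of 3454 simulated germ cell genes, 100 of 100 with a 2-fold change, 100 of 100 with a 4-fold change and 0 of 3235 unchanged genes passed, and of 3444 simulated granulosa genes 100 of 100, 98 of 100 and 0 of 3234 did. Intervals covered the true value for 94.8% and 95.5% of genes with at least 50 CPM in the simulated library labelled MLT. A simulated 2-fold shift of 23 proliferation genes gave medians of 0.96 and 0.91, both at percentile 100 of random lists. Of the other lists, 1 of 22 and 1 of 21 lay outside the central 95% of random lists. Immune cells, with 90 cells in the library labelled DEHP_MLT, were too few for an expression comparison, and erythroid, mixed and unnamed clusters were left out of it.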

Results

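Ovaries of C57BL mouse pups at postnatal day 3, when primordial follicles have just formed around single oocytes, were profiled cell by cell in 2 libraries. The library labelled MLT came from pups whose mothers had received melatonin with DMSO in place of DEHP, and the library labelled DEHP_MLT from pups whose mothers had received DEHP and then melatonin. The question stated for the study is what melatonin does in offspring ovaries when the mother is exposed to DEHP during primordial follicle formation. With these 2 groups the comparison can show what differs with DEHP in the presence of melatonin, since a group without melatonin is not among the libraries. The library labelled MLT held 5277 barcodes and 80657690 UMIs, with a median of 10834 UMIs and 3670 genes per barcode, and the library labelled DEHP_MLT held 4819 barcodes and 117355739 UMIs, with a median of 13161 UMIs and 3820 genes. The lowest total of any barcode was 2031 UMIs in the former and 6923 in the latter, so the deposited tables had different floors, and 1193 barcodes labelled MLT lay below the higher one. The median mitochondrial share was 3.39% and 3.32%. The group names follow the sample titles, which the names of the deposited tables contradict, and every direction given here would reverse if the titles were wrong.

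The first comparison asked which cell types made up each ovary sample. Cells named as germ cells and red blood cell precursors took a larger share of the cells in the library labelled DEHP_MLT. Stroma, endothelium and perivascular cells took a smaller one, in part because erythroid cells took so much of the total. Germ-cell-like cells, marked by Ddx4, Dazl and Sycp3 among others, were 4.0% of cells labelled MLT (208 of 5199, interval 3.48% to 4.57%) and 9.80% of cells labelled DEHP_MLT (472 of 4816, 8.98% to 10.7%), a log2 ratio of 1.29. Erythroid-like cells with haemoglobin transcripts and Alas2, the haem synthesis enzyme of red cell precursors, were 0.673% (35 cells, 0.469% to 0.935%) and 14% (676 cells, 13.1% to 15%), a log2 ratio of 4.38. Of the cells outside the erythroid clusters, germ cells were 4.03% and 11.4%.

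Among somatic cells, stroma-like cells were 53.0% of the library labelled MLT (2754 cells, 51.6% to 54.3%) and 44.2% of the library labelled DEHP_MLT (2130 cells, 42.8% to 45.6%), but 53.3% and 51.4% of the cells outside the erythroid clusters. Endothelial-like cells were 3.46% (180 cells, 2.98% to 4.0%) and 2.14% (103 cells, 1.75% to 2.59%). Perivascular or smooth-muscle-like cells were 4.67% (243 cells, 4.12% to 5.28%) and 3.32% (160 cells, 2.83% to 3.87%), and immune-like cells 2.89% (150 cells, 2.45% to 3.38%) and 1.87% (90 cells, 1.51% to 2.29%). Granulosa-like cells, the supporting cells of the follicle, were 14.8% (772 cells, 13.9% to 15.8%) and 8.72% (420 cells, 7.94% to 9.55%), a log2 ratio of -0.77. Surface-epithelium-like cells were 4.73% (246 cells, 4.17% to 5.34%) and 7.43% (358 cells, 6.71% to 8.21%), a log2 ratio of 0.65. Their leading genes included Lgr5 and Gng13, which are also granulosa markers and epithelial pregranulosa genes in the lists used here. Granulosa markers stood there at 0.404 of their level in granulosa cells. The surface class may thus hold epithelial pregranulosa cells, and the granulosa class may not hold all supporting cells. Of the cells outside the erythroid clusters, endothelial cells were 3.49% and 2.49%, perivascular cells 4.71% and 3.86% and immune cells 2.90% and 2.17%, each with overlapping intervals. The granulosa and surface directions depended on the clustering, because the ratios became 0.06 for granulosa and -0.21 for surface cells when each library was clustered on its own.

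Other clusters, as called here, belonged almost wholly to 1 library. Cells with both germ and granulosa or surface markers were 6.06% of the library labelled DEHP_MLT when germ markers led (292 cells) and 2.18% when somatic markers led (105 cells), against 0.0962% (5 cells) and 0.0577% (3 cells) of the library labelled MLT. Unnamed clusters were 11.6% of the library labelled MLT (603 cells) and 0.208% of the other (10 cells), and their median of 3372 UMIs per cell in the former lies below the floor of the latter. The main unnamed cluster, with 565 cells labelled MLT and 2 labelled DEHP_MLT, held germ and granulosa markers at 0.303 and 0.506 of the level in their own clusters. That passes the mixed rule, but its few UMIs left it unnamed first. The small mixed counts labelled MLT thus depend on the order of the rules. The germ-led direction turned (log2 ratio -0.95) when each library was clustered on its own, and with the same UMI floor in both libraries the somatic-led class was 2.70% and 2.80%, a log2 ratio of 0.06. That class then pooled a cluster led by Lgals2 and Mt1 with 5 cells labelled MLT and 134 labelled DEHP_MLT and another, led by Tsix and other noncoding RNAs as the main unnamed cluster was, with 105 and 1. Where a cluster lies almost wholly in 1 library, a cell type cannot be separated from a property of that library.

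**Figure D1:**
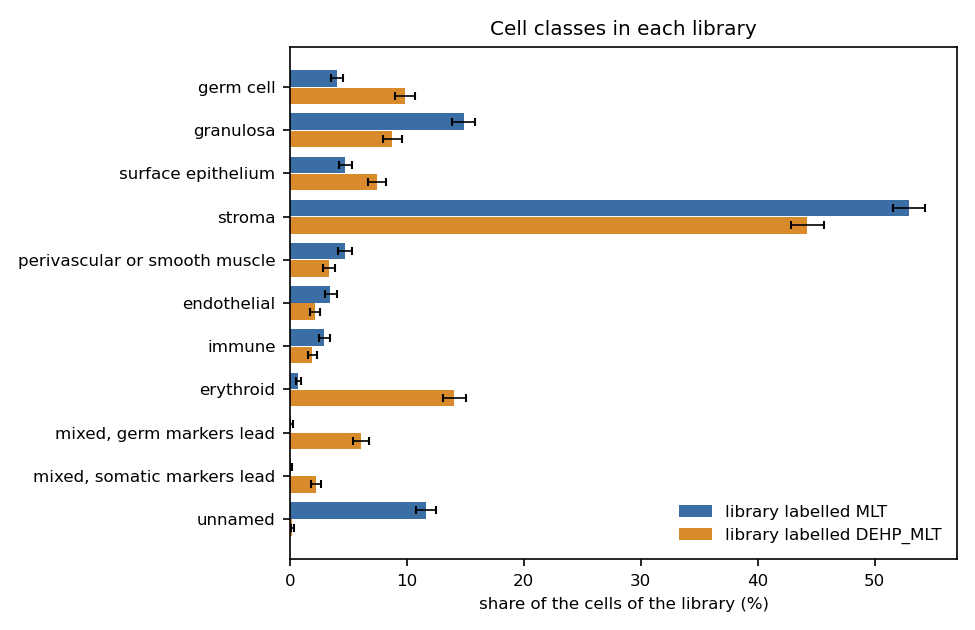
Share of cells in each cell class (horizontal bars, percent of the cells kept) in the library labelled MLT and the library labelled DEHP_MLT, with exact 95% binomial intervals that cover counting error only. Erythroid cells were 0.673% and 14% of cells, and germ cells 4.0% and 9.80%.

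In germ cells, the comparison asked which oocyte programmes differ with DEHP while melatonin is given. The genes furthest apart were interferon-induced genes, higher in the library labelled MLT. Gbp7, a GTPase induced by interferon, stood at 69.2 CPM in germ cells labelled MLT and 0.757 CPM in germ cells labelled DEHP_MLT, a log2 ratio of -5.32. B2m, the light chain of MHC class I, stood at 109 and 26.7 CPM (-1.99), Bst2, an antiviral membrane protein, at 75.3 and 19.7 CPM (-1.88), and Irf1, an interferon-induced transcription factor, at 50.5 and 16.2 CPM (-1.58). Ifitm3, an interferon-induced membrane protein also used as an early germ cell marker, gave -1.57, and Elobl, which led a germ cell sub-cluster together with growing-oocyte genes, gave -1.97. Bst2 and Ifitm3 stood at 13.2% and 14.8% of the level in other cells labelled MLT, close to the 13.9% below which 90% of somatic markers lay. These values rest on 8741076 and 33017506 UMIs from 208 and 472 cells, and the median germ cell held 12320.5 UMIs in the library labelled MLT and 74941.5 in the library labelled DEHP_MLT. The tables had different UMI floors, so these medians are not compared. With the same floor the class held 117 and 470 cells.

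In the other direction, germ cells labelled DEHP_MLT had more RNA of Tsga8, a germ-cell-specific gene, at 80.6 against 28.9 CPM (log2 ratio 1.45), and of the replication-dependent histone gene Hist1h2ap at 362 against 163 CPM (1.15). Prdx4, a peroxiredoxin of the secretory pathway, stood at 365 against 182 CPM (1.0), and Syce3, part of the synaptonemal complex that holds meiotic chromosomes together, at 91.2 against 55.3 CPM (0.71). Further genes at this end were Dusp9 (1.01), Hmga1 (0.90), Fmr1nb (0.88), the metallothionein Mt1 (0.78) and Fcgbp (0.74). Sox4, Ccnd2 and Kctd14 were lower in germ cells labelled DEHP_MLT (-1.36, -1.35 and -1.33), but germ cells held them at only 7.49%, 7.34% and 8.33% of the level in other cells labelled MLT, near the 7.94% median of somatic markers there, and their ratios turned to 0.72, 0.55 and 0.67 when the mixed germ-led cluster was added.

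Of the 23 lists with a value in germ cells, 8 lay outside the central 95% of random lists. The growing-oocyte list, which holds zona pellucida and maternal-effect genes, had a median of -0.51 (percentile 0), and 6 of its 19 measured members were at least 1.5-fold higher in the library labelled MLT, among them Nlrp14 (-1.09) and Npm2 (-1.0), with Uchl1 at 0.37. This leaves out 292 mixed germ-led cells labelled DEHP_MLT and 5 labelled MLT. Those labelled DEHP_MLT held Npm2, Khdc3 and Zp3 at 114, 61.9 and 323 CPM, against 47.7, 30.4 and 207 CPM in germ cells of that library. The median kept its sign with that cluster added. The early germ cell and pluripotency list had a median of -0.46 (percentile 0.4) over 5 members, with Ifitm3 at -1.57 and Pou5f1, the pluripotency factor of germ cells, at -1.05. DNA damage repair had a median of -0.28 (percentile 0.05), with Mdc1 at -0.84 and Atm at -0.62, and DNA and histone methylation -0.28 (percentile 0.15), with Suz12 at -0.76 and the maintenance methyltransferase Dnmt1 at -0.71. Immediate-early and heat shock genes had a median of -0.23 (percentile 0.45), with Nr4a1 at -1.40, and this turned to 0.46 with the mixed germ-led cluster. Glycolysis and hypoxia genes were the only list outside the range on the side of the library labelled DEHP_MLT, with a median of 0.20 (percentile 100), Eno1 at 0.52 and Pkm at 0.48.

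The meiotic prophase, oocyte transcription factor and antioxidant lists lay inside that range in germ cells, and the pregranulosa lists outside it. Meiotic prophase genes had a median of -0.03 (percentile 51.6) with Tex101 at 1.78 and Mlh3 at -0.55, and oocyte transcription factors 0.09 (percentile 91.7) with Figla, the activator of zona genes, at 0.24. Antioxidant defence had a median of 0.07 (percentile 96.0), with Prdx4 at 1.0 and Mgst1 at -1.44, and it turned to -0.16 with equal weight per cell. The 2 pregranulosa lists had medians of -1.14 (bipotential, percentile 0) and -0.71 (epithelial, percentile 0) in germ cells, where granulosa markers stood at 8.33% of the other cells' level in the library labelled MLT and 5.78% in the library labelled DEHP_MLT. Both turned with the mixed germ-led cluster, to 0.49 and 0.88.

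Germ cell stages were compared at 2000 UMIs per cell, since the exposure window covers meiotic prophase and the formation of follicles. Meiotic prophase genes gave 8.55 UMIs per cell (8.16 to 8.96) in the library labelled MLT and 8.01 (7.76 to 8.27) in the library labelled DEHP_MLT, with 8.53 and 8.0 per 2000 UMIs without thinning. Oocyte transcription factors gave 7.36 (6.99 to 7.73) and 7.78 (7.53 to 8.04), with 7.32 and 7.59 without thinning, and growing-oocyte genes 22.0 (21.4 to 22.6) and 19.7 (19.3 to 20.1), with 21.9 and 19.6 without thinning. The thinned intervals of the first 2 measures overlapped, and those of the growing-oocyte level were apart. The mixed germ-led cluster, with Npm2 and Zp3 among its leading genes, was left out. It held 292 cells labelled DEHP_MLT and 5 labelled MLT. Stage levels were not measured with these cells added, so the growing-oocyte difference may depend on leaving them out. Without thinning the intervals of all 3 were apart, with 8.44 to 8.62 against 7.95 to 8.04 for meiotic prophase genes and 7.24 to 7.40 against 7.55 to 7.64 for oocyte transcription factors. With the same UMI floor those of meiotic prophase genes were apart at 2000 UMIs as well (8.31 to 9.39 against 7.65 to 8.16). Sub-clustering gave 1 group of germ cells. At the higher resolution 3 groups appeared. The group in which Elobl, Npm2, Khdc3 and Zp3 led held 143 of 208 cells labelled MLT and 172 of 472 cells labelled DEHP_MLT, with medians of 6338 and 34371.5 UMIs per cell. A group led by Tex101, Taf7l and Tsga8 held 7 and 59 cells. These sizes are not read as a difference, because Elobl, Npm2, Tex101 and Tsga8 themselves differ between the libraries.

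In granulosa cells, the comparison asked how the somatic cells that enclose the oocyte differ, without any that the surface class may hold. MHC class II and interferon-induced genes were far higher in the library labelled MLT. H2-Ab1, a chain of MHC class II, stood at 378 CPM and 1.01 CPM (log2 ratio -7.56), H2-Aa at 268 and 1.26 CPM (-6.90), Cd74, the invariant chain of MHC class II, at 590 and 4.88 CPM (-6.65) and H2-Eb1 at 305 and 2.69 CPM (-6.37). The interferon-induced GTPases Gbp2 and Gbp4 gave -4.84 and -4.75, the immunoproteasome subunits Psmb8 and Psmb9 -4.74 and -4.23, H2-Q7 -4.78 and Ly6a -4.44. Members of the MHC, haemoglobin, Stfa and Oas1 families are near-identical in sequence, so how UMIs were divided among them is uncertain. These genes defined a cluster of 196 granulosa cells present in the library labelled MLT alone, of which 143 remained granulosa-like and 47 became surface-like when cells were clustered without such genes.

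Higher in granulosa cells labelled DEHP_MLT were the BMP-responsive inhibitors of differentiation Id2 at 78.7 against 31.8 CPM (1.28) and Id3 at 225 against 117 CPM (0.94). Ftl1, the ferritin light chain, stood at 2682 against 1633 CPM (0.72), Tmsb10 at 1700 against 1056 CPM (0.69), and Ttyh2, Hist1h2ap and Snhg1 gave 0.82, 0.81 and 0.72. S100a8 and S100a9, abundant proteins of neutrophils, gave 1.10 and 0.94 and were also higher in every other class. Without the MHC-led cluster S100a8 (2.96) and S100a9 (2.67) led the 10 highest, which still included Id2 (1.43) and Id3 (0.88), joined by the metallothioneins Mt1 (1.21) and Mt2 (0.87) and the stress factor Atf3 (0.99). The lowest were then Bc1 (-2.32), Tsix (-1.76), H2-D1 (-1.69), Hist1h1b (-1.53), H2-K1 (-1.48), Pdia3 (-1.29), Chp2 (-1.19), Rasd1 (-1.16), Cpq (-1.11) and the Notch target Hes1 (-1.11).

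Of the 22 lists with a value in granulosa cells, 11 lay outside the central 95% of random lists. ER stress genes had a median of -0.51 (percentile 0), and 8 of 16 members were at least 1.5-fold higher in the library labelled MLT, led by the folding factors Pdia3 (-1.44) and Sdf2l1 (-1.26), while Ddit3, a transcription factor of the stress response, gave 0.82. DNA damage repair and proliferation each had a median of -0.38, with Xrcc5 at -0.88 and the cyclin Ccnd1 at -1.21. Steroidogenesis had a median of -0.37, with Hsd17b7 at -0.93, and PPAR and lipid genes -0.36, with the fatty acid carrier Fabp5 at -1.66. BMP and TGF-beta signalling had a median of 0.13 (percentile 99.9) with Id2 and Id3 highest, and glycolysis 0.13 (percentile 99.8) with Pdk1 at 0.46. The epithelial pregranulosa list had a median of -0.61, with Krt19 at -2.49, but -0.11 without the MHC-led cluster, which held surface-like cells.

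The bipotential pregranulosa list, which holds Foxl2 and the markers of early follicle cells, had a median of -0.07 in granulosa cells (percentile 54.7). The growing-oocyte list had a median of -0.35 there, where germ cell markers stood at 0.046 of their level in germ cells. PI3K and mTOR signalling (0.05, percentile 98.4) and the circadian clock (0.10, percentile 97.7) lay just outside the range, and turned to -0.01 without the MHC-led cluster and to -0.04 with equal weight per cell.

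In the remaining classes the comparison asked whether the differences were shared. MHC class II genes were again among the lowest in the library labelled DEHP_MLT, and Id genes among the highest. In stroma the BMP target Id1 stood at 429 against 74.6 CPM (log2 ratio 2.51), the transcription factor Klf4 at 249 against 63.8 CPM (1.95) and the stress-induced phosphatase Dusp1 at 331 against 94.0 CPM (1.80), while H2-Ab1, Cd74 and H2-Eb1 gave -7.28, -7.01 and -7.00. Stroma was split by library, with 1500 of its cells labelled DEHP_MLT and 29 labelled MLT in the cluster led by Tcf21, and 135 and 1477 in the cluster led by Col4a4 and Ogn. A further cluster, led by Iigp1 and Ifit3, held 541 cells labelled MLT and 3 labelled DEHP_MLT, and without it Id1, Klf4 and Dusp1 gave 2.39, 2.04 and 1.83, and H2-Ab1 -5.23.

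In perivascular or smooth muscle cells Ren1, the renin gene of vessel-wall cells, stood at 170 against 27.9 CPM (2.56), Id1 at 301 against 63.0 CPM (2.24) and the Notch target Nrarp at 103 against 23.5 CPM (2.09). Pericytes were 94 of the 243 cells labelled MLT and 103 of the 160 cells labelled DEHP_MLT, so the make-up of the class differed. In the pericyte cluster alone Ren1, Id1 and Nrarp gave 1.79, 1.48 and 1.34, and in the smooth muscle cluster alone 1.21, 2.83 and 0.12. H2-Ab1 had 138 UMIs in the library labelled MLT and 0 in the other, so it was at least 32.7-fold higher in the former, and the chemokine Cxcl10 had 204 UMIs and 1 UMI, a ratio of 145 (25.8 to 5763). Gbp4 had 141 UMIs and 1 UMI, a ratio of 100 (17.7 to 3992). In endothelial cells the imprinted transcript H19 stood at 261 against 82.2 CPM (1.66), Id1 at 917 against 335 CPM (1.45) and Gja4, a gap junction protein of arteries, at 88.3 against 32.4 CPM (1.42). The chemokine Cxcl9 had 1179 UMIs and 1 UMI there, a ratio of 847 in favour of the library labelled MLT (152 to 33476), Cd74 had 1304 and 2 UMIs, a ratio of 468 (129 to 3871), and H2-Ab1 had 573 and 3 UMIs, a ratio of 137 (46.7 to 667). In surface cells Id2 stood at 63.5 against 19.9 CPM (1.63) and Ttyh2 at 59.1 against 26.2 CPM (1.14), and H2-Ab1, Cd74 and Bc1 gave -4.28, -2.70 and -2.42.

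The interferon and MHC genes were highest in part of the cells labelled MLT, in every somatic class, and higher in the median cell as well. With cells clustered without these genes, 60 or more of every 10000 UMIs came from the 34-gene set in 144 of 741 granulosa cells labelled MLT (19.4%, 16.6% to 22.5%), 533 of 2641 stroma cells (20.2%, 18.7% to 21.8%) and 50 of 267 surface cells (18.7%, 14.2% to 23.9%). The share was 21.2% of endothelial cells (38 of 179), 24.5% of pericytes (23 of 94), 13.7% of smooth muscle cells (25 of 183) and 60.4% of immune cells (90 of 149). In the library labelled DEHP_MLT it was 1.85% of granulosa cells, 1.27% of stroma cells, 0.980% of surface cells and 17.8% of immune cells. The immune cells differed in make-up, with 23 of 150 labelled MLT and 46 of 90 labelled DEHP_MLT in the neutrophil-led cluster, and in the cluster led by C1qa alone the shares were 69.3% (60.5% to 77.2%) and 25% (13.2% to 40.3%). Of germ cells, 1 of 212 labelled MLT and 0 of 481 labelled DEHP_MLT reached the level. The median cell labelled MLT held 9.17 UMIs of the set per 10000 in stroma, 19.2 in granulosa, 21.5 in endothelial and 8.75 in germ cells, against 3.49, 9.74, 11.2 and 2.56 in the library labelled DEHP_MLT. The level divides a range, and over the 6 somatic classes 105 of 4105 cells labelled MLT and 110 of 3134 cells labelled DEHP_MLT lay near it, between 40 and 80. Interferon genes were not confined to the library labelled MLT. With the stricter cell filter a stroma cluster with Gbp3, Ifitm3 and Usp18 among its leading genes held 129 cells labelled DEHP_MLT and 0 labelled MLT. The stroma cluster led by Iigp1 then held 3 and 520.

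**Figure D2:**
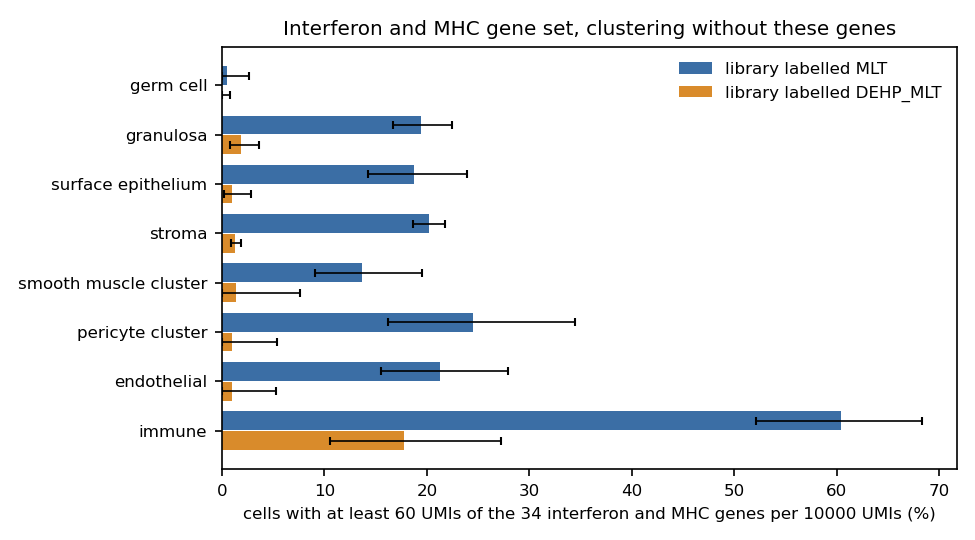
Share of cells (horizontal bars, percent) in which at least 60 of every 10000 UMIs came from the 34 interferon and MHC genes, by cell class from a clustering without these genes, in the library labelled MLT and the library labelled DEHP_MLT, with exact 95% binomial intervals that cover counting error only. The share was 20.2% of stroma and 19.4% of granulosa cells labelled MLT, against 1.27% and 1.85% of those labelled DEHP_MLT.

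Across the 6 classes, some gene lists moved the same way everywhere. Glycolysis and hypoxia genes had a higher median in the library labelled DEHP_MLT in 6 of 6 classes, from 0.13 to 0.43, outside the central 95% of random lists in all 6, with Ldha at 0.80 in stroma and 1.05 in perivascular cells. ER stress genes were higher in the library labelled MLT in 6 of 6 classes (medians -0.54 to -0.19, outside the range in 5), as were DNA damage repair genes (-0.59 to -0.28, outside in 5) and DNA and histone methylation genes (outside in 4, lowest in surface cells). The directions of these 4 lists held in all alternatives tried. Random lists matched to the ER stress, repair and methylation lists also had negative medians in each class, so a negative sign alone says little. In granulosa cells methylation genes had a median of -0.17 against -0.12 for random lists (percentile 24.8). Steroidogenesis (outside in 1), PPAR and lipid (outside in 1) and bipotential pregranulosa genes (outside in 3) were negative in 6 of 6 classes as well. Also higher in the library labelled MLT in all 6 classes were the nuclear RNAs Malat1 (-0.69 to -1.16) and Kcnq1ot1 (-0.64 to -0.74), the mitochondrial transcripts mt-Nd6 (-1.64 to -2.84) and mt-Atp8 (-1.52 to -2.33), and AY036118 and Gm42418, genes chosen after their values were seen. A direction shared by all classes therefore cannot be separated from a property of the library. Apoptosis genes (-0.17 to -0.02), antioxidant genes (-0.18 to 0.09) and melatonin and hormone receptors (-0.43 to -0.06) lay inside the range in all 6 classes, and the median of each changed sign in at least 1 class under TMM scaling.

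Other lists differed from class to class. Notch signalling had a median of 0.32 in perivascular cells, with Hey2 at 1.09 and Notch3 at 0.88, but it turned to -0.12 in the pericyte cluster alone and to -0.12 in the smooth muscle cluster alone. Autophagy had 0.16 in perivascular cells, and both lists lay inside the range elsewhere. Cholesterol synthesis had a median of 0.18 in endothelial cells (percentile 99.3), with Mvd at 0.64. Immediate-early and heat shock genes had medians of 0.19 in stroma, with Dusp1 at 1.80 and Atf3 at 0.87, 0.25 in perivascular cells and -0.33 in surface cells. Proliferation had a median of -0.58 in surface cells, with Top2a at -1.41 and Mki67 at -1.24, and 0.29 in perivascular cells, and BMP and TGF-beta signalling -0.32 in perivascular cells although Id1 gave 2.24. In the smooth muscle cluster alone the perivascular medians turned to -0.10 for immediate-early genes, -0.25 for proliferation and 0.16 for BMP and TGF-beta signalling. Differences between classes were not tested. The early germ cell list could otherwise be measured only in endothelial cells (-0.79, 3 members). In surface cells the oocyte transcription factor list had a median of 0.54, with germ cell markers there at 0.048 of their level in germ cells.

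**Figure D3:**
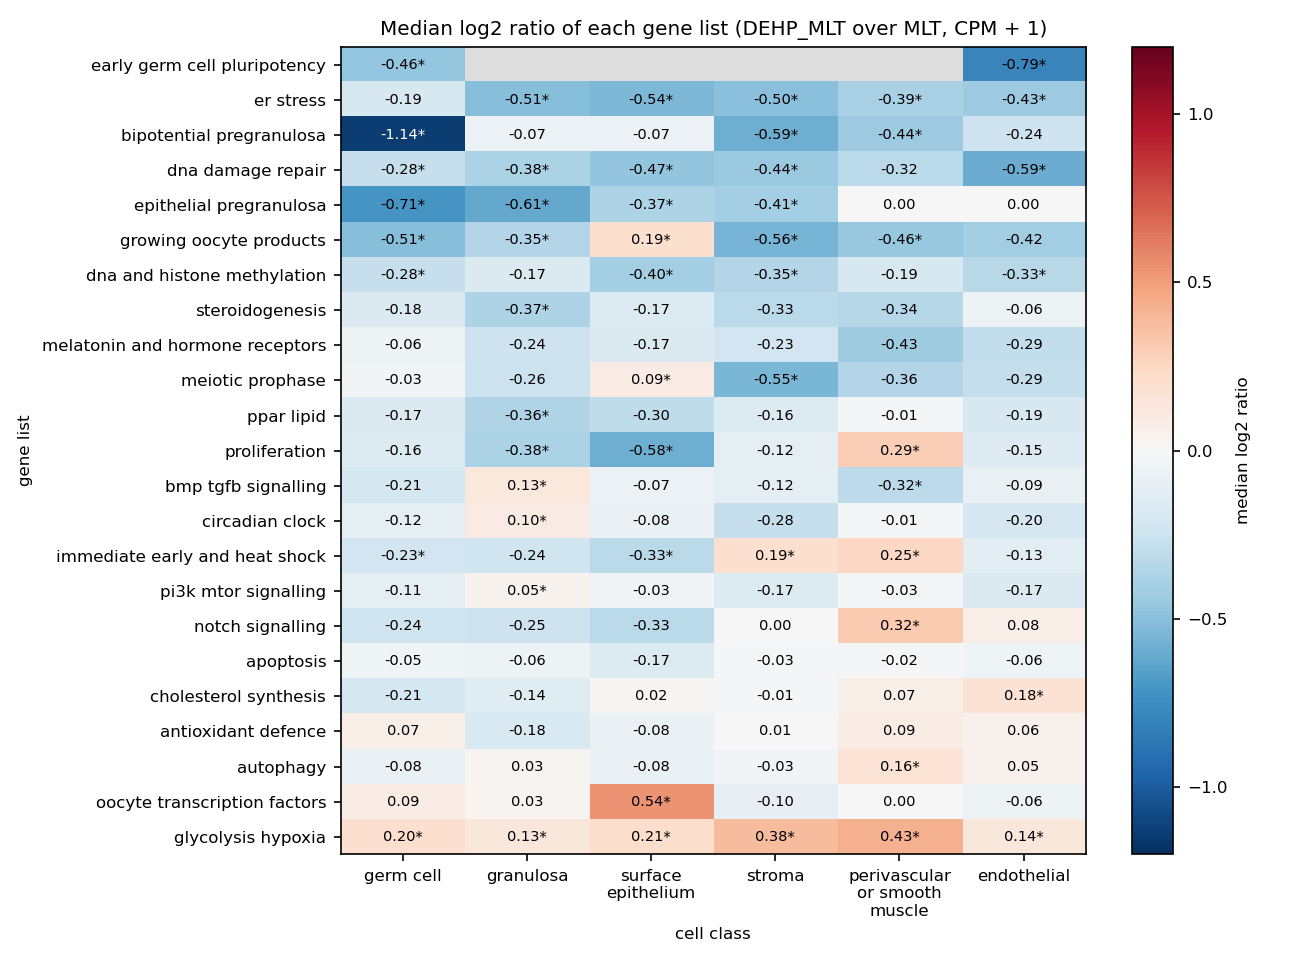
Median log2 ratio (DEHP_MLT over MLT, CPM + 1) of each gene list in each cell class, with red for higher in the library labelled DEHP_MLT and blue for higher in the library labelled MLT. An asterisk marks medians outside the central 95% of random lists and grey marks lists with fewer than 3 measured members, and the glycolysis and hypoxia list is positive in 6 of 6 classes.

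The cell cycle was compared as the share of cells with any UMI of Mki67, Top2a, Ccnb1 or Cdk1 at 2000 UMIs per cell. Stroma cells gave 30.3% (28.6% to 32.1%) in the library labelled MLT and 27.0% (25.2% to 29.0%) in the library labelled DEHP_MLT, surface cells 28.9% (23.3% to 35.0%) and 21.2% (17.1% to 25.8%), and endothelial cells 40.6% (33.3% to 48.1%) and 34% (24.9% to 44.0%). Perivascular cells gave 21.4% (16.4% to 27.1%) and 29.4% (22.4% to 37.1%), and germ cells 61.1% (54.1% to 67.7%) and 52.8% (48.1% to 57.3%). Granulosa cells were lowest, at 15.2% (12.7% to 17.9%) and 11.0% (8.13% to 14.3%). In each class the intervals of the 2 libraries overlapped. With the same UMI floor those of surface cells were just apart, at 33.0% (26.6% to 39.9%) and 21.6% (17.1% to 26.6%). Without thinning the shares were 62.4% and 60.9% in stroma, 73.2% and 70.1% in surface cells, 75.6% and 74.8% in endothelial cells, 51.4% and 60.6% in perivascular cells, 65.3% and 58.8% in granulosa cells and 92.8% and 98.9% in germ cells. Oocytes do not divide at this stage, so the germ cell share is not read as division.

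A set of genes differed the same way in all 6 classes. At least 1.5-fold higher in the library labelled DEHP_MLT were 9 genes. They included the red cell genes Alas2 (0.60 to 5.13) and Slc4a1 (1.02 to 4.42), the neutrophil genes S100a8 (1.10 to 2.30), S100a9 (0.94 to 2.25) and Stfa1 (0.78 to 2.36), and Cd24a (1.10 to 2.15). Of 38 genes higher in the library labelled MLT, H2-Ab1 spanned -4.11 to -7.56, Cd74 -2.70 to -7.63 and the noncoding RNA Bc1 -1.94 to -2.96. Haemoglobin transcripts were 0.0713% of stroma UMIs labelled MLT and 0.914% of those labelled DEHP_MLT, and 0.0328% and 0.667% in germ cells, but 1.38% and 1.44% in endothelial cells. Ribosomal protein transcripts were 19.1% and 23.5% of UMIs in granulosa cells, 23.3% and 27.0% in stroma and 21.1% and 21.8% in germ cells. Mitochondrial transcripts were 7.24% and 8.92% in granulosa cells and 5.21% and 5.52% in germ cells, but 3.24% and 3.10% in stroma.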

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

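All tests in this part were chosen after the result was seen, except the one on Gbp7 and Igtp in germ cells, whose outcome was written down before it was measured.

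Part of the cells labelled MLT carried interferon and MHC transcripts, and that library held 298 UMIs of Ifng, the gene of interferon gamma, outside the comparisons above, against 0 in the library labelled DEHP_MLT. RNA of immune cells, free or in the same droplet, is argued against, because the interferon-led clusters held the immune markers at a median of 0.259% of the immune cluster's level but Cd74 at 119%. The pattern is consistent with some of the ovaries, if several were pooled, carrying the response in 6 somatic classes, since the share of such cells ran from 13.7% in smooth muscle cells to 24.5% in pericytes with no intervals of these 6 apart (the upper limit of smooth muscle, 19.5%, lies just under the 19.8% of all 6), although immune cells stood apart at 60.4% (52.1% to 68.3%), and since 10.6% (5.22% to 18.7%) of 94 deeply read germ cells labelled MLT held Gbp7 and Igtp at 2 or more UMIs per 10000, against 0 of 376, although germ cells lie at the low end and the median stroma cell was higher too (9.17 against 3.49 UMIs of the set per 10000), which a response in some ovaries alone leaves unexplained. A first form of the test on somatic classes used classes that these genes had themselves shaped. It gave 0 of 149 smooth muscle cells and spoke against the explanation, and it was redone with classes from a clustering without these genes. In germ cells, free somatic RNA is argued against as the only origin, because 10 of 29 genes of the set outside MHC class II (interval 17.9% to 54.3%), Gbp7 and Irf1 among them, lay above 13.9% of the other cells' level, where 10% of somatic markers do; for the other 19, Bst2 (13.2%), Gbp2 (12.8%), Isg15 (9.42%) and Ifit3 (8.6%) among them, it stays open, for MHC class II genes (11.4%) their own expression and free RNA cannot be told apart, and with 1 library per treatment the treatment stays open as the origin, as does an infection, which was not tested.

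In the library labelled DEHP_MLT, 292 cells had germ markers in the lead together with granulosa and surface markers and 105 had somatic markers in the lead, classes outside the comparisons of expression. A random germ cell and a random somatic cell in the same droplet would give partners in the ratio of the somatic classes. Of 854 cells with germ markers at 0.25 or more of the germ cell level, whatever their cluster, 54 held at least 50% of a stroma cell's marker UMIs. At least 50% of a granulosa or surface cell's was held by 197. The ratio was 0.274 (0.199 to 0.372, and at most 0.901 as upper limit at 9 combinations of these levels). The classes stand at 1.81 with every mixed cell counted as granulosa or surface. The library labelled MLT also fell short of its class ratio. Its 723 cells with germ markers exceed its 208 germ cells, though, and the partner level was a UMI count set from cells labelled DEHP_MLT. Cells with few UMIs can rarely reach that count, so the library labelled MLT is no like control. The ratio in the library labelled DEHP_MLT itself moved from 0.0797 to 0.737 with the levels chosen. The test cannot decide, and random pairs stay open. Free somatic RNA raised by the same factor for every class is argued against as the only origin. Stroma markers and haemoglobin, which did not enter the naming of the cluster, were 3.07-fold (2.63 to 3.54) and 1.97-fold (1.67 to 2.36) above their level in germ cells, but granulosa markers 11.5-fold (10.4 to 12.6). Granulosa and surface markers did enter the naming, so a high factor was required of them. The mast cell genes Cma1 and Tpsb2 rose more, 23.6-fold and 31.4-fold after adding 1 CPM, so free RNA of particular cells stays open. Germ cells that stayed attached to granulosa or surface cells remain open, without separate support, since the only values bearing on them are these same counts, and cells labelled MLT also had fewer stroma than granulosa or surface partners (32 and 47 of 723 cells, a ratio of 0.681 where the classes stand at 2.68). Compared with germ cells of the same library, these cells had Zp3 at 1.56-fold, Npm2 at 2.35-fold and Khdc3 at 2.0-fold the level, Sycp3 at 0.693-fold, and also the mast cell gene Tpsb2 at 31.4-fold, which attached granulosa cells do not account for; whether the dissociation or the treatment differed is open with 1 library per group, and a biological explanation was not tested.

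In the library labelled DEHP_MLT, 676 cells were erythroid, outside the comparisons of expression. The lower UMI floor of the library labelled MLT is argued against as the origin, because the log2 ratio of the shares was still 4.08 with the same floor in both libraries. More blood of the same composition cannot be told apart from a change in red cells alone, because with that floor the neutrophil-led cluster held 1 cell labelled MLT and 46 labelled DEHP_MLT, a ratio of shares of 38.9 (6.65 to 1571) beside 16.9 (12 to 24.6) for erythroid cells. Without the floor it held 23 and 46 cells, a ratio of 2.16 (1.28 to 3.73) beside 20.9 (14.8 to 30.2), which speaks the other way but counts cells labelled MLT with a median of 5758 UMIs, under the 6923 at which the other library begins. Lysis of red cells in 1 preparation and a difference in blood formation were not tested and stay open.

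Signals in clusters that no comparison used were 565 cells labelled MLT in an unnamed cluster with few UMIs and 38 cells labelled MLT in an unnamed cluster led by the mast cell genes Cma1, Cpa3 and Tpsb2 (10 with the same UMI floor in both libraries). Some gene lists had medians of opposite sign in different classes, each outside the central 95% of random lists, and the differences between the classes were not tested. BMP and TGF-beta signalling gave -0.32 in perivascular or smooth muscle cells and 0.13 in granulosa cells. Growing-oocyte genes gave -0.56 in stroma and 0.19 in surface cells, and meiotic prophase genes -0.55 in stroma and 0.095 in surface cells, classes that held germ cell markers at 0.039 to 0.051 of their level in germ cells. The surface values turned with equal weight per cell (-0.20 and -0.0053), growing-oocyte genes also with members from 1 CPM (-0.029) and meiotic prophase also with doublets kept (-0.022) and the same floor (-0.12), while meiotic prophase in stroma turned to 0.022 with the total without mitochondrial, ribosomal protein and haemoglobin genes. Immediate-early and heat shock genes gave -0.33 in surface cells and 0.25 in perivascular or smooth muscle cells, and proliferation genes -0.58 and 0.29. In the smooth muscle cluster alone the perivascular values of these 3 lists (BMP and TGF-beta, immediate-early and proliferation) turned to 0.16, -0.10 and -0.25.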

How the results depend on the processing

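The share of the named germ cell class kept its direction in 9 of 9 alternatives (log2 ratio 1.25 to 1.77), as did the endothelial (-0.72 to -0.39) and immune shares (-0.69 to -0.40), and the erythroid share in 8 of 8 (3.92 to 5.56). With each library clustered on its own the germ class was 4.06% of cells labelled MLT and 9.78% of those labelled DEHP_MLT. The mixed germ-led class was then 11.7% and 6.04%, so the germ direction does not extend to all cells with germ markers. Of the named genes, 14 to 20 of 20 were still at least 1.5-fold apart the same way in germ cells, 18 to 20 of 20 in granulosa cells and 6 of 6 in each other class, except 5 of 6 in the smooth muscle cluster alone. The other parts of the naming rule were not checked again. Over single genes 503 of 506 alternative values kept their direction, and over the lists outside the central 95% of random lists 452 of 469, while of all list values 1064 of 1182 did. Shares moved as follows (log2 ratios). With the stricter cell filter granulosa gave -1.01 and erythroid 5.56. With doublets kept the mixed germ-led class gave 4.23, and at Leiden resolution 1.0 it gave 2.63. With each library clustered on its own granulosa turned to 0.064, surface to -0.21 and the mixed germ-led class to -0.95, while stroma gave -0.17, perivascular -1.21 and unnamed -0.88. In that setting 223 MHC-led cells labelled MLT stayed unnamed, 443 cells labelled MLT were called granulosa, 394 surface, and 607 with few UMIs mixed. With the same UMI floor germ cells gave 1.77, granulosa -1.03, stroma -0.41, the mixed germ-led class 3.75, the mixed somatic-led class 0.055 (2 unlike clusters, with 105 and 5 cells labelled MLT and 1 and 134 labelled DEHP_MLT) and unnamed -0.56. Clustered without interferon genes surface gave 0.31, and outside erythroid cells stroma gave -0.052. With the same floor the ratio of median UMIs was 0.10 and that of median genes turned to -0.057. Without thinning the germ cell cycle ratio was 0.093, and at sub-clustering 0.6 the largest group held 68.8% of germ cells labelled MLT.

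With the mixed germ-led cluster added to germ cells Sox4 turned to 0.72, Ccnd2 to 0.55 and Kctd14 to 0.67. The bipotential pregranulosa list turned to 0.49, the epithelial one to 0.88 and immediate-early genes to 0.46. That cluster holds Kctd14 at 14.7-fold and Atf3 at 9.83-fold the level of germ cells, after adding 1 CPM to both. Elsewhere the cause was not tested. In granulosa cells the circadian clock turned to -0.040 with equal weight per cell and PI3K and mTOR signalling to -0.012 without the interferon-led cluster. In surface cells meiotic prophase turned to -0.0053 with equal weight, -0.022 with doublets kept and -0.12 with the same floor, and growing-oocyte genes to -0.20 with equal weight and -0.029 with members from 1 CPM. In stroma meiotic prophase turned to 0.022 with the total without mitochondrial, ribosomal protein and haemoglobin genes. In perivascular cells 9 lists lay outside the range but 4 in the pericyte and 4 in the smooth muscle cluster alone. In pericytes alone Notch turned to -0.12 and the bipotential pregranulosa list to 0.035, and in smooth muscle alone Notch to -0.12, BMP and TGF-beta signalling to 0.16, proliferation to -0.25 and immediate-early genes to -0.10. No paired analysis was possible because each group has 1 library and the labels pair no animals. Depth limits perivascular and endothelial cells most, with 1910471 and 2751698 UMIs in the library labelled DEHP_MLT.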

Other observations

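The genes named here were chosen after their values were seen. The cytotoxic genes named here were higher in the immune cells of the library labelled MLT, with 1 library per group. In the cluster led by C1qa, a UMI of Gzma was held by 17.3% of cells labelled MLT and 2.27% of those labelled DEHP_MLT. For Nkg7 the shares were 21.3% and 4.55%. The intervals of the 2 libraries overlapped for both genes. Those of Gzmb (17.3% against 0 of 44 cells) were apart. The T cell gene Cd3e had overlapping intervals as well. In the cluster led by C1qa, 11.0% (6.16% to 17.8%) of cells labelled MLT and 9.09% (2.53% to 21.7%) of those labelled DEHP_MLT held a UMI of it. In the immune cluster led by C1qa, 25 of 127 cells labelled MLT (19.7%, 13.2% to 27.7%) held a UMI of Ifng, against 0 of 44 cells labelled DEHP_MLT, where the share of cells with a UMI has an upper limit of 8.04%. The median immune cell held 10597 and 11711.5 UMIs, and 0.182% of stroma cells labelled MLT held a UMI of Ifng. Gzma and Gzmb, the granzymes of cytotoxic lymphocytes, had 1480 and 660 UMIs in the library labelled MLT and 9 and 0 in the library labelled DEHP_MLT, and Nkg7 had 706 and 51. Neutrophil transcripts went the other way, with S100a8 at 10282 UMIs in the library labelled MLT and 35571 in the library labelled DEHP_MLT, and a UMI of it in 8.24% and 34.2% of stroma cells.

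Mast cell transcripts were present in both libraries. Cma1, a mast cell protease, had 7682 UMIs in the library labelled MLT and 7993 in the library labelled DEHP_MLT, Cpa3 had 2668 and 2443, and Tpsb2 had 4466 and 5511. A cluster led by these genes held 38 and 8 cells, and 10 and 8 with the same UMI floor in both libraries. In the mixed germ-led cells labelled DEHP_MLT, Cma1 stood at 179 CPM against 6.63 CPM in germ cells, Mt1 at 534 against 61.7 CPM and the stress factor Atf3 at 48.1 against 4.0 CPM.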
